A study of Mus musculus with 6 samples.

How the data were processed

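Liver RNA was extracted with Trizol from flash-frozen tissue and made into strand-preserving libraries with a directional Illumina kit, per the labels' protocols. The deposited table holds FPKM values that the authors computed for each gene and library. The submitters' processing notes name HISAT2, HTSeq, DESeq2 and StringTie and the genome build mm10, without versions or the role of each tool, and which of them made the FPKM values is not given in the sources used here. Whether reads were counted by strand is not given either, so genes that overlap on opposite strands cannot be told apart with certainty. Each of the 6 value columns was matched to a sample by the group and replicate number in its name. All 24034 gene identifiers were found in GENCODE mouse release 21, from which chromosome, position and strand were taken, and 24012 had the same symbol there. No pair of libraries held identical values, and 1317 genes were at 0 in all libraries.

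FPKM is scaled for length and library, so it is not a count. Low values were searched for the step that 1 read would give, taken as the commonest product of FPKM and exonic length in a library. Between 24.1% and 25.5% of low values were whole multiples of that step within a tolerance of 0.02 reads, too few to recover counts, and no count model was fitted. The step gave relative depths of 19100000 to 24600000 read equivalents. At the filter of 0.5 FPKM, a gene with 2000 exonic bases would hold 19.1 to 24.6 such reads, so genes near the filter are measured with little precision. Since FPKM is relative to all other genes in a library, a change in abundant genes shifts the values of the rest.

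Genes with a mean of 0.5 FPKM or more over the 6 libraries were kept (13250 genes), and log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with 2 groups, no block and eBayes with a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. The 40 gene lists covered metabolism, sex bias, stress and immune responses, liver zonation and markers of other cell types. They were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the lists, 37 had 3 or more measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37. Markers of pancreatic acinar cells, of mesothelium and gallbladder and of skeletal muscle had 2, 2 and 1 measured members and were not tested. Camera with an estimated correlation and fry were run as alternatives. None of the 14 lists that passed did so with an estimated correlation, where the smallest adjusted p was 0.385, and fry, which tests whether the genes of a list move on balance one way, gave 2 lists.

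The genes named are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of 1 FPKM or more and no overlap between the groups. Added to these are 4 members with the smallest p of each list that passed or had 3 or more members past the threshold, up to 2 members of each other list, Xist and 4 Y-linked genes, and the 3 genes with the highest mean. Lncenc1 was to be named first and was not analysed here. A planned comparison with the authors' own calls was not made. The fit was tested on simulated data for this comparison with 13076 genes, of which 199 were changed. It recovered 77.8% of genes changed by 1 on the log2 scale and 100% of those changed by 2, with 16 false among 193 calls and 0 sign errors. When only the glycolysis list was shifted by 1 in simulated data, 1 of 37 lists was called. Simulated genes varied independently, and no simulated library stood apart from the others. In several real lists the genes varied together, with estimated correlations of 0.591 for the acute phase list and 0.391 for the male-biased list. These simulations therefore do not show how often genes or lists are called falsely here.

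Alternatives were pseudocounts of 1 and 0.1, no filter and a filter at a mean of 1 FPKM, median-of-ratios scaling, quantile normalization, eBayes without a trend, robust eBayes, array weights (statmod 1.5.0), the replicate number as a block, and leaving out each library in turn. All 10 splits of the 6 libraries into 3 and 3 were fitted. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.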

Results

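RNA sequencing was done on liver from C57BL/6 mice at 25 weeks of age. Of the 6 libraries, 3 came from wild type animals (WT) and 3 (HO) from animals whose genotype label gives the same non-wild-type allele on both copies of the long non-coding RNA gene Lncenc1. They were read as homozygous mutants, since the series' design text speaks of knockout mice, and what the allele changes in the gene is not given in the sources used here. The comparison asked how the adult liver transcriptome differed when this RNA, described in the study's title as one of early embryos, was mutated. Expression was given as FPKM (fragments mapped to a gene, scaled for transcript length and for the mapped fragments of the library) for 24034 genes. The libraries were alike in summed FPKM, but the middle of their values was lower in HO. The FPKM values summed to between 495570 and 518218 per library, and the 10 most abundant genes took 18.5% to 21.1% of that sum. Genes at 1 FPKM or more numbered 11637 to 11667 in the WT libraries and 11321 to 11471 in the HO libraries. The median FPKM was 0.8525 to 0.8789 in WT and 0.7422 to 0.7884 in HO, a shift that the main fit did not correct. Relative depth, read from the spacing of the low values, was 19100000, 23500000 and 21900000 read equivalents in WT and 19900000, 24600000 and 22600000 in HO. Xist stayed at or under 0.0522 FPKM in all 6 libraries, and Ddx3y at or above 16.7 FPKM, so each library had the pattern of a male. Kdm5d (2.89 to 3.65 FPKM), Uty (2.24 to 3.14 FPKM) and Eif2s3y (20.5 to 27.5 FPKM), also on the Y chromosome, were present in all 6. Lncenc1 lies on chromosome 13, from 97434970 to 97497007 on the plus strand (mm10). Its own RNA was not analysed here, so the genotypes rest on the labels and were not checked. The labels give no substrain of C57BL/6. A difference of genetic background between the groups therefore cannot be told apart from the mutation for any result below. The labels do not state that the libraries of a group came from separate animals, and the p-values measure the spread between these samples.

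Among 13250 genes tested, 43 rose and 108 fell in HO (limma with Benjamini-Hochberg adjustment at 0.05). Of 37 gene lists, 14 passed with camera at its preset correlation, none with camera at an estimated correlation (smallest adjusted p = 0.385, with 4 at an unadjusted p under 0.05) and 2 with fry. The genes that fell included Cd36, Acot3 and Acaa1b of fatty acid uptake and oxidation and the female-biased Cyp2b9. Those that rose included the male-biased Selenbp2 and Serpina1e and, from the acute phase list, Saa4. A change of at least 1 on the log2 scale was reached by 31 of the genes that rose and 57 of those that fell, and 132 of the 151 changed genes were protein coding. In each of the 151 the 3 HO values lay all above or all below the 3 WT values. The same separation was seen for 3692 of all tested genes, or 27.9%. Random labels give 10% on average, but genes vary together, so a single split can lie far from that average. An unadjusted p under 0.05 was reached by 2850 of all tested genes, or 21.5%. With such a share, many lists hold members that pass when adjusted over the list alone. The bile acid list, which did not pass with camera, had 3 higher and 6 lower. Such counts, given below, are not adjusted over the 37 lists and are weak evidence for a list. On the first principal component, which held 44.8% of the variance, the WT libraries lay at -31.3, -26.4 and -10.1 and the HO libraries at 14.04, 29.8 and 23.9. On the second, with 19.7%, HO replicate 1 lay at -33.5 and the others between 1.23 and 17.2. The balance of directions depended on scaling: median-of-ratios scaling gave 66 genes higher and 66 lower, and quantile normalization 56 higher and 72 lower, against 43 and 108. The number of changed genes also depended on single libraries. It was 9 without WT replicate 1, 6 without WT replicate 2 and 259 without WT replicate 3. It was 203 without HO replicate 1, 35 without HO replicate 2 and 15 without HO replicate 3.

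The steepest falls were those of Mup10, Cyp2b9, Nnt, Rad51b and Acot3. Values here and below are mean FPKM ± SD of 3 libraries per group, and log2 changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Mup10, one of the major urinary proteins that carry pheromones in mouse urine, went from 1925 ± 1242 in WT to 2.44 ± 3.75 in HO, a log2 change of -10.02 ± 0.89 (SE, limma adjusted p = 0.0143). It lies on chromosome 4 from 60578260 to 60582199. Cyp2b9, a P450 enzyme with higher expression in females, went from 51.2 ± 34.6 to 1.53 ± 0.436 (log2 change -4.39 ± 0.56, limma adjusted p = 0.0284). It is encoded on chromosome 7 from 26173411 to 26210661. Nnt, which encodes the mitochondrial transhydrogenase that makes NADPH, dropped from 31.8 ± 11.4 to 1.14 ± 0.344, with a log2 change of -4.27 ± 0.26 and the smallest adjusted p of the named genes (limma, 0.00721). Nnt is on the same chromosome as Lncenc1, from 119335448 to 119408997 on chromosome 13, and 21.8 Mb away. The recombination gene Rad51b (chromosome 12, 79297282 to 79814690) fell from 7.82 ± 2.04 to 0.537 ± 0.247, and the peroxisomal thioesterase Acot3 (chromosome 12, 84052144 to 84060402) from 6.34 ± 1.34 to 0.490 ± 0.275. The non-coding Gm34654, Cyp2a22, Slc22a27, Hamp2 and Abcd2 made up the rest of the 10 largest falls, with log2 changes of -2.75, -2.60, -2.51, -2.16 and -2.06. Hamp2 is a paralogue of the iron hormone hepcidin, and Abcd2 carries very long-chain acyl groups into peroxisomes.

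The largest rise was that of Selenbp2, from 67.0 ± 43.6 FPKM in WT to 803.2 ± 197.5 in HO, a log2 change of 3.73 ± 0.40 (SE, limma adjusted p = 0.0230). The gene, which encodes a selenium-binding protein, lies on chromosome 3 from 94693556 to 94704413. Tff3, a secreted trefoil factor, rose by 2.66 ± 0.42 on the log2 scale (limma adjusted p = 0.0454). Serpina1e, which encodes a form of alpha-1 antitrypsin, went from 1265 ± 658.7 to 7132 ± 651.4 (log2 change 2.62 ± 0.33, limma adjusted p = 0.0284). Scara5, a ferritin receptor, rose by 2.57 ± 0.43, and Socs3, a feedback inhibitor of cytokine signalling, by 2.51 ± 0.30. Cyp7b1, an oxysterol hydroxylase of the alternative pathway of bile acid synthesis, went from 68.3 ± 24.0 to 266.3 ± 66.1 (log2 change 1.97 ± 0.27, limma adjusted p = 0.0329). Cyp21a1, a steroid hydroxylase best known from the adrenal gland, was at 0.328 ± 0.111 in WT and 2.63 ± 0.104 in HO (log2 change 1.93 ± 0.15, limma adjusted p = 0.0109). Mup12, the antisense gene Gm11963 and the interleukin receptor gene Il1r1 rose by 1.82, 1.78 and 1.75 on the log2 scale. All 20 of these genes kept their sign under each alternative tried. When a library was left out this had to be so, as their groups did not overlap. Of the 38 named genes that passed, only 4 still did without WT replicate 1, 3 without WT replicate 2, 11 without HO replicate 2 and 8 without HO replicate 3. Reads of Mup, Cyp2, Ugt2b, Gst and Serpina1 genes can be shared with near-identical copies. The reads of Cyp21a1, Acot3, Acot4, Slc22a27, Me1, Cyp7b1, Il1r1, Cyp2a22 and Acaa1b can be shared with overlapping annotated genes such as Tnxa and Dlec1, so the values of all these genes are uncertain.

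**Figure D1:**
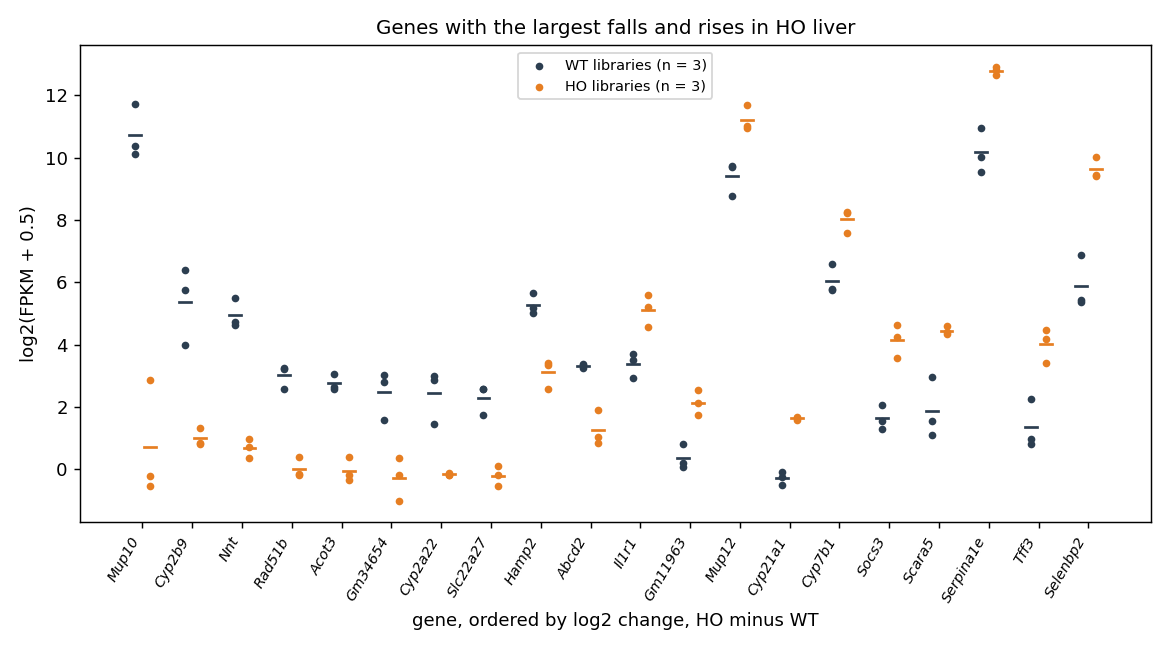
Expression of the 10 genes with the largest falls and the 10 with the largest rises in HO, as log2(FPKM + 0.5) on the vertical axis, with 1 point per library (WT dark, HO orange, 3 each) and a bar at the mean. The 3 HO points of each gene lie all below or all above its 3 WT points, and the spread within a group is widest for genes such as Mup10, with 1925 ± 1242 FPKM in WT and 2.44 ± 3.75 FPKM in HO.

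Male-biased liver genes rose as a list in HO, and 3 female-biased genes fell. Of 17 measured male-biased genes, 3 rose (Selenbp2, Serpina1e and Ugt2b38) and none fell, with 14 higher when adjusted over the list alone and a median log2 change of 0.85. The list rose relative to other genes (camera adjusted p = 8.87e-17), with an adjusted p = 0.385 under an estimated correlation. The number of its genes that rose was 5 with median-of-ratios scaling, 10 with array weights, 7 without WT replicate 3, and 0 when WT replicate 1, WT replicate 2, HO replicate 2 or HO replicate 3 was left out. Ugt2b38, a glucuronosyltransferase, went from 1.86 ± 0.626 FPKM to 7.08 ± 1.19 (log2 change 1.70 ± 0.21, limma adjusted p = 0.0284). The complement component C6 was at 70.4 ± 24.7 in WT and 159.3 ± 11.4 in HO, just short of the threshold (limma adjusted p = 0.0526). Of 8 measured female-biased genes, 3 fell (Cyp2b9, Abcd2 and Cyp2a4) and none rose, with 4 lower and 2 higher when adjusted over the list alone and a median log2 change of -1.13. The list as a whole did not pass (camera adjusted p = 0.296, and 0.627 as the adjusted p with an estimated correlation). Its median depended on the filter and on WT replicate 2: it was -0.09 over 6 genes at a mean of 1 FPKM or more, where the direction of the camera test turned to up, -0.08 over 16 genes with no filter, and -0.41 without WT replicate 2. Of this list 4 genes fell without WT replicate 3, 1 without HO replicate 3, and 0 without WT replicate 1, WT replicate 2 or HO replicate 2. Cyp2a4, another P450, went from 1.43 ± 0.386 to 0.0191 ± 0.0331, while the female-biased Cyp2c40 was at 0.338 ± 0.188 in WT and 1.96 ± 0.663 in HO (limma adjusted p = 0.0503). Cyp2c40 passed as higher under 5 of the settings that used all libraries: a filter at 1 FPKM, both scaling alternatives, robust eBayes and array weights. The growth hormone and IGF axis, with 13 genes and none past the threshold, did not pass its test either (camera adjusted p = 0.240). Its member Prlr had 25.5 ± 5.64 FPKM in WT and 13.03 ± 0.911 in HO (limma adjusted p = 0.0571).

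Acute phase genes rose as a list in HO livers, with lower values for most of them in HO replicate 1 than in the other HO libraries. Of 26 measured, 2 rose (Socs3 and Saa4) and none fell, 12 were higher when adjusted over the list alone, and the median log2 change was 1.02. Without HO replicate 1, 15 rose and the median was 1.63. The number that rose was 12 with array weights, 1 without HO replicate 2 (median 0.80), and 0 without WT replicate 1, WT replicate 2 or HO replicate 3 (medians 0.91, 0.93 and 0.79). In 23 of the 26 genes HO replicate 1 had the lowest HO value, and it exceeded all WT libraries in 12. Saa1 and the metallothionein Mt1, chosen after their values were seen, were at 111.0 and 55.5 FPKM in HO replicate 1, at 2525 and 2145 in HO replicate 2, and at 2630 and 1311 in HO replicate 3, with WT means of 117.5 ± 48.5 and 24.2 ± 5.65. The list passed with camera adjusted p = 8.50e-16, with an adjusted p = 0.569 under an estimated correlation. Saa4, a constitutive serum amyloid A, went from 171.8 ± 59.5 FPKM to 500.7 ± 81.1 (log2 change 1.58 ± 0.24, limma adjusted p = 0.0372). Serpina3n was at 179.0 ± 25.1 in WT and 655.3 ± 323.0 in HO (limma adjusted p = 0.0868), and the chemokine gene Cxcl1 at 10.9 ± 5.22 and 45.2 ± 9.47 (limma adjusted p = 0.0541). Interferon-stimulated genes rose as a list (camera adjusted p = 1.30e-09, adjusted p = 0.385 with an estimated correlation). Of these 38 genes, Rsad2 and Mx2 rose and none fell, 8 were higher when adjusted over the list alone, and the median was 0.32 (0.21 without WT replicate 2). The number that rose was 5 with median-of-ratios scaling, 4 with quantile normalization, 7 with array weights, and 0 without WT replicate 1, WT replicate 2, HO replicate 2 or HO replicate 3. Rsad2, an antiviral effector, and Mx2, annotated as a polymorphic pseudogene, had log2 changes of 0.81 ± 0.11 and 0.90 ± 0.15. Usp18, which removes ISG15 from proteins, was at 6.68 ± 0.474 in WT and 12.6 ± 2.28 in HO (limma adjusted p = 0.0515), and the GTPase Iigp1 at 106.1 ± 3.45 and 170.9 ± 27.0 (limma adjusted p = 0.0531). The unfolded protein and integrated stress response list also rose (20 genes, median 0.24, or 0.12 without HO replicate 2, camera adjusted p = 2.65e-04, adjusted p = 0.627 with an estimated correlation). No member passed over all genes and 2 were higher when adjusted over the list alone. Of its members, Xbp1 was at 100.1 ± 32.5 in WT and 206.4 ± 43.2 in HO and Chac1 at 1.93 ± 0.242 and 3.84 ± 0.580, Ddit3 was at 12.01 ± 2.33 and 7.56 ± 1.53 and Atf4 at 45.8 ± 2.35 and 34.0 ± 5.90, none of which passed (limma adjusted p = 0.0811, 0.0526, 0.125 and 0.123).

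Of 30 measured genes of fatty acid oxidation and ketogenesis, 4 fell in HO (Acot3, Acot4, Acot2 and Acaa1b) and none rose, 16 were lower when adjusted over the list alone, and the median log2 change was -0.38. The number that fell was 1 without WT replicate 1, 0 without WT replicate 2, 9 without WT replicate 3, 2 without HO replicate 3 and 16 with array weights. The list passed with camera adjusted p = 2.51e-06, with an adjusted p = 0.385 under an estimated correlation. Acaa1b, a peroxisomal thiolase, went from 1083 ± 112.4 FPKM to 461.7 ± 57.3 (log2 change -1.23 ± 0.13, limma adjusted p = 0.0211). The acyl-CoA thioesterase Acot4 went from 20.0 ± 0.785 to 5.79 ± 1.77 and Acot2 from 5.94 ± 1.21 to 2.55 ± 0.110. The 3 thioesterases of this list that fell lie close together on chromosome 12, from 83987861 for Acot2 to 84060402 for Acot3. Lipid droplet and steatosis genes also fell as a list, with 2 of 18 past the threshold, 8 lower when adjusted over the list alone and a median of -0.52 (camera adjusted p = 2.73e-04, adjusted p = 0.385 with an estimated correlation). Cd36, a fatty acid transporter, went from 48.9 ± 2.86 to 19.5 ± 1.78 (log2 change -1.31 ± 0.10, limma adjusted p = 0.0109), and the lipoprotein receptor gene Vldlr from 1.05 ± 0.182 to 0.267 ± 0.0743 (limma adjusted p = 0.0484). Cidea, a lipid droplet protein, was at 11.8 ± 1.46 in WT and 1.72 ± 1.99 in HO (limma adjusted p = 0.0765). It is also counted in the adipocyte list, where 4 of 6 measured genes were lower when adjusted over the list alone. Of the lipid droplet and steatosis genes, 3 fell without WT replicate 3 and 6 with array weights. Only 1 of them fell when WT replicate 1, WT replicate 2, HO replicate 2 or HO replicate 3 was left out. The call of Vldlr was lost with median-of-ratios scaling and with quantile normalization.

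The 2 lists of lipid synthesis fell in HO by camera at its preset correlation. Fatty acid and triglyceride synthesis had 1 of 22 genes past the threshold, 6 lower when adjusted over the list alone and a median log2 change of -0.35, or -0.55 without HO replicate 3 (camera adjusted p = 0.0292, adjusted p = 0.627 with an estimated correlation). The gene that fell was Me1, the cytosolic malic enzyme, from 86.2 ± 6.18 FPKM to 46.0 ± 6.05 (log2 change -0.91 ± 0.12, limma adjusted p = 0.0284). Its call was lost with no filter. Fasn was at 80.7 ± 16.9 in WT and 40.3 ± 5.65 in HO, and Acly at 79.0 ± 6.72 and 54.9 ± 2.41 (limma adjusted p = 0.0526 for both). None of 25 genes of cholesterol synthesis and uptake passed over all genes and 10 were lower when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 6.06e-04, adjusted p = 0.627 with an estimated correlation). Its members with the smallest p included Insig1, at 149.6 ± 22.4 in WT and 75.5 ± 17.0 in HO, Mvd at 18.3 ± 5.20 and 6.95 ± 2.58, and Hmgcs1 at 163.8 ± 59.8 and 55.1 ± 20.5 (limma adjusted p = 0.0526, 0.0750 and 0.0778). The list of fatty acid synthesis did not pass without WT replicate 3 (camera adjusted p = 0.208) or without HO replicate 2 (0.0512), nor with array weights (0.134). Nuclear genes of oxidative phosphorylation fell by a small amount as a list (37 genes, 36 with a negative log2 change, median -0.23, or -0.13 with either scaling alternative, camera adjusted p = 1.32e-05, adjusted p = 0.627 with an estimated correlation). Among them Ndufb8, a subunit of respiratory complex I, passed on its own, with 93.2 ± 8.66 in WT and 60.8 ± 0.997 in HO (limma adjusted p = 0.0362), and 2 genes were lower when adjusted over the list alone. The call of Ndufb8 was lost with both scaling alternatives, with no filter and with no mean-variance trend. For all genes tested, the median log2 change was -0.09. The 13 mitochondrially encoded genes had a median of -0.17, or -0.07 with median-of-ratios scaling, and did not pass (camera adjusted p = 0.167, with 0.0470 without HO replicate 1 and 0.00331 with quantile normalization).

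Xenobiotic metabolism fell as a list in HO, close to the threshold. Of 27 genes, Cyp2c38, Cyp3a11 and Gstm1 fell and none rose, and when adjusted over the list alone 16 were lower and 5 higher, with a median log2 change of -0.54 (camera adjusted p = 0.0498, adjusted p = 0.627 with an estimated correlation). The number that fell was 0 when WT replicate 1, WT replicate 2 or HO replicate 3 was left out. Without WT replicate 3, 6 fell and 1 rose, and with array weights 9 and 2. Cyp3a11, a major drug-metabolizing P450, went from 444.1 ± 62.0 FPKM to 222.5 ± 30.6, Cyp2c38 from 30.2 ± 9.02 to 7.02 ± 1.00, and the glutathione transferase Gstm1 from 586.9 ± 46.8 to 309.3 ± 53.3 (limma adjusted p = 0.0339, 0.0261 and 0.0360). The receptor gene Nr1i3 was at 92.5 ± 5.68 and 65.2 ± 5.51 (limma adjusted p = 0.0582). NRF2 antioxidant targets fell as a list (15 genes, median -0.28, camera adjusted p = 5.12e-03, adjusted p = 0.627 with an estimated correlation). None passed over all genes and 5 were lower when adjusted over the list alone. Its members Gpx4 and Nqo1 were at 175.2 ± 21.6 and 4.52 ± 1.03 in WT and at 113.4 ± 8.02 and 1.71 ± 0.648 in HO (limma adjusted p = 0.0552 and 0.0769). Amino acid catabolism and urea cycle genes ranked higher than other genes as a list (camera adjusted p = 4.70e-03, adjusted p = 0.627 with an estimated correlation). Their median log2 change was only 0.07 over 25 genes, 16 positive and 9 negative, against -0.09 for all genes tested. This median ranged from 0.00 without HO replicate 1 to 0.17 with median-of-ratios scaling. With fry, which tests for a move on balance, the list did not pass (adjusted p = 0.403). Cps1, the first enzyme of the urea cycle, passed on its own, from 399.0 ± 41.3 to 729.1 ± 111.3 (log2 change 0.86 ± 0.13, limma adjusted p = 0.0422), and 2 genes were higher when adjusted over the list alone. The call of Cps1 was lost with no filter and with no mean-variance trend. The bile acid list did not pass (19 genes, median -0.07, or 0.02 with median-of-ratios scaling, camera adjusted p = 0.695), but Cyp7b1 in it rose, and the transporters Abcc3 (70.5 ± 2.45 to 47.5 ± 3.06) and Slco1a4 (10.2 ± 2.28 to 4.33 ± 0.846) fell, with 3 higher and 6 lower when adjusted over the list alone. Without WT replicate 3, 3 of its genes rose and 4 fell, without HO replicate 1, 0 and 1, and with any other library left out, 0 and 0. The calls of Abcc3 and Slco1a4 were lost with both scaling alternatives, and that of Gstm1 with median-of-ratios scaling. Cyp7a1, the rate-limiting enzyme of classic bile acid synthesis, was at 44.2 ± 13.4 in WT and 10.4 ± 5.78 in HO (limma adjusted p = 0.0526). The xenobiotic list did not pass without WT replicate 1, WT replicate 2, HO replicate 1 or HO replicate 3 (camera adjusted p = 0.0704, 0.141, 0.0530 and 0.119), nor with a pseudocount of 1, a filter at 1 FPKM or no mean-variance trend (0.0517, 0.0981 and 0.0608), nor the amino acid list without WT replicate 3 or HO replicate 1 (0.0588 and 0.105).

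**Figure D2:**
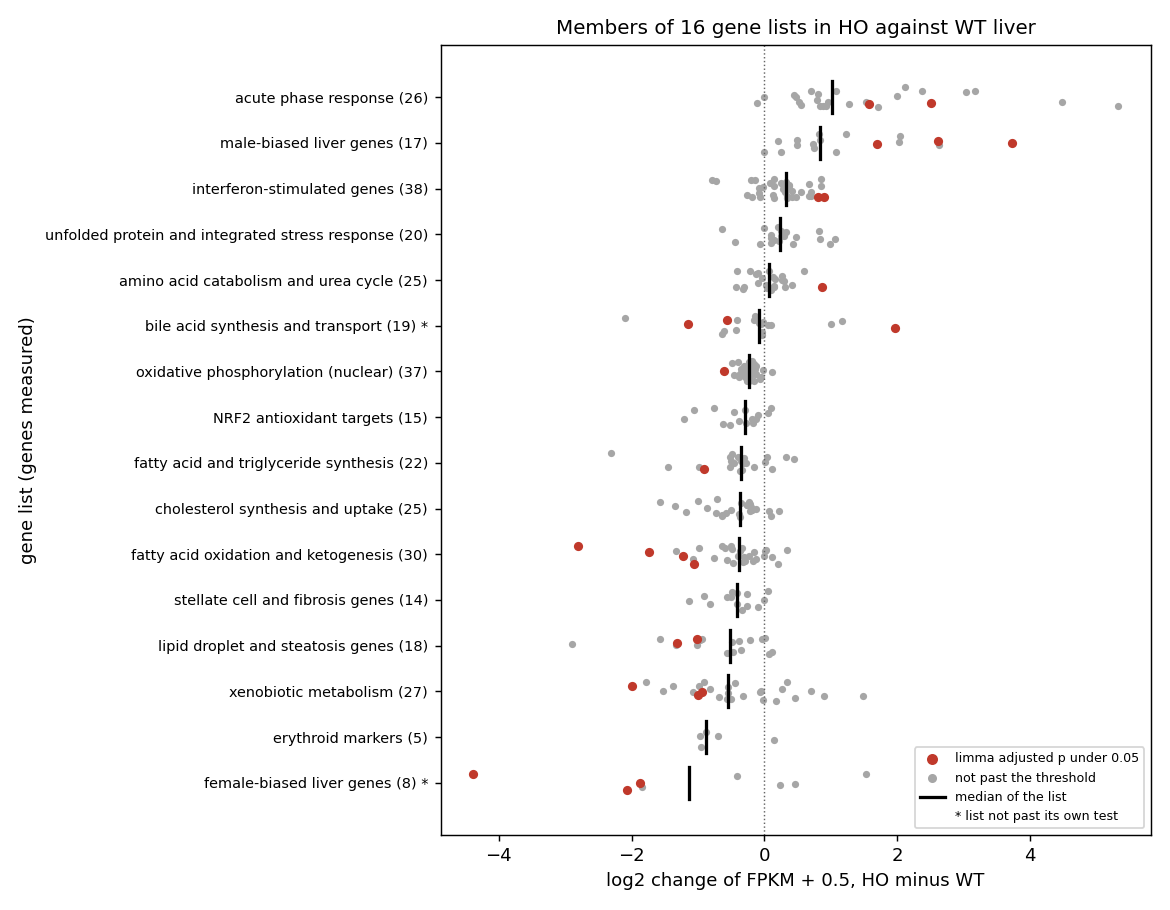
Log2 change of FPKM + 0.5, HO minus WT, on the horizontal axis for the measured members of 16 gene lists, with 1 point per gene (red past the limma threshold, grey not) and a black bar at the median. Medians run from 1.02 for the acute phase list to -1.13 for the female-biased list, a value that holds at the filter of 0.5 FPKM and was -0.09 at a filter of 1 FPKM. That list, like the bile acid list, did not pass its own test and is marked with an asterisk.

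Among markers of other cell types, those of stellate cells and erythroid cells fell as lists in HO. Stellate cell and fibrosis genes fell as a list (14 genes, median log2 change -0.41, camera adjusted p = 5.12e-03, adjusted p = 0.627 with an estimated correlation). None passed over all genes and 7 were lower when adjusted over the list alone. Its members Dcn and Col3a1 were at 72.1 ± 6.61 and 8.74 ± 3.32 FPKM in WT and at 51.3 ± 5.57 and 3.61 ± 0.948 in HO (limma adjusted p = 0.0813 and 0.0842). Erythroid markers fell as a list of 5 (median -0.88, camera adjusted p = 0.0428, adjusted p = 0.627 with an estimated correlation), with 4 lower when adjusted over the list alone and none past the threshold over all genes. The beta-globin gene Hbb-bt was at 45.5 ± 4.13 in WT and 23.7 ± 7.25 in HO (limma adjusted p = 0.0747). This list did not pass without WT replicate 1, WT replicate 3, HO replicate 2 or HO replicate 3 (camera adjusted p = 0.0533, 0.0829, 0.116 and 0.0570), nor with a filter at 1 FPKM or no mean-variance trend (0.0504 and 0.0544). None of the lists of Kupffer cell markers (13 genes), sinusoidal endothelial markers (13), monocyte and inflammatory macrophage markers (7), cholangiocyte markers (6) and lymphocyte markers (7) passed (camera adjusted p = 0.167, 0.572, 0.296, 0.932 and 0.809), and none had a member past the threshold. The Kupffer list passed without WT replicate 2 (camera adjusted p = 0.0245). The 3 measured neutrophil markers and the 6 adipocyte markers did not pass either (camera adjusted p = 0.179 and 0.141), although the neutrophil list did without HO replicate 1 (0.0470) and with no filter (0.0115), and the adipocyte list with quantile normalization (0.0467). When adjusted over the list alone, 1 of the neutrophil markers was higher and 4 of the adipocyte markers were lower. In the adipocyte list Cfd was at 49.9 ± 6.13 in WT and 5.86 ± 5.74 in HO (limma adjusted p = 0.0637).

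The other lists showed no difference that passed. Pericentral and periportal hepatocyte genes, 14 each, had camera adjusted p = 0.809 and 0.366, and within the periportal list Cps1 rose. Lipoprotein and lipid transport (21 genes, camera adjusted p = 0.693) held Apoc2, at 88.0 ± 23.6 FPKM in WT and 36.0 ± 4.63 in HO (limma adjusted p = 0.0503). Gluconeogenesis and glycogen (0.339), glycolysis (0.695), circadian clock (0.0642), heat shock (0.0981), immediate early genes (0.666), p53 targets (0.0642), cell cycle (0.693), cytosolic ribosomal proteins (0.572) and nuclear-retained RNAs (0.852) are given here with their camera adjusted p. None of these had a member past the threshold. The circadian clock list passed without WT replicate 3 or without HO replicate 3 (camera adjusted p = 3.75e-05 and 0.0404) and with array weights (0.0378), the p53 list without WT replicate 3 or HO replicate 1 (0.00750 and 0.0470), and with no filter, median-of-ratios scaling, quantile normalization or array weights (0.0106, 0.0378, 0.0449 and 0.0202), and the heat shock list without HO replicate 1 (0.0470). The 3 genes with the highest mean FPKM were Alb (32399.8 ± 1084 in WT, 27996 ± 2318 in HO), Apoa2 (12919.9 ± 1367 and 8684 ± 747.7) and mt-Co1 (9649 ± 710.3 and 9161 ± 713.1), none of which passed (limma adjusted p = 0.385, 0.0811 and 0.758).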

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

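The alternatives here were planned before the data were examined. The 151 genes changed in HO (43 higher, 108 lower) became 100 (23 higher) with a pseudocount of 0.1, and 77 (18 and 59) without a mean-variance trend. Array weights gave 941 (249 and 692). Without a filter the count was 40 (7 and 33), with 22717 genes in place of 13250 in the adjustment. Median-of-ratios scaling gave 66 higher and 66 lower, with 109 of the 151 among its calls. The replicate number as a block gave 25 genes (10 and 15). Same-numbered libraries deviated from their group means with correlations of 0.0661, -0.0282 and 0.0147. These give no sign that the numbers pair samples, but with 3 libraries per group they cannot exclude it. Under the block the xenobiotic list did not pass (0.0607), while the circadian clock and p53 lists did (0.0332 and 0.0420). Leaving out 1 library gave 6 to 259 changed genes (2 to 91 higher, 4 to 168 lower). These fits have fewer samples, yet the count was above 151 without WT replicate 3 (259) and without HO replicate 1 (203). The cause was not tested for these or for the other settings. No sign among the 151 turned in any fit, and each of those tested had an unadjusted p under 0.05 in every fit. This is weak support, since the genes were picked by p in the same libraries. Their WT and HO values do not overlap, so leaving out a library could not turn a sign. Gene lists changed in HO numbered 14, and 12 to 17 under the settings that kept the preset correlation, but 0 with camera at an estimated correlation (4 at an unadjusted p under 0.05) and 2 with fry (lipid droplet, adjusted p = 0.00799, and fatty acid oxidation, 0.0155). Camera at an estimated correlation, which kept none of the 14 calls, and fry are left out of the next counts. Of the other comparisons of single lists with their main result, 19 lost a call, 18 gained one and 554 did neither. For single named genes these numbers were 326, 94 and 1799. The alternatives could not give a value for Lncenc1. Thresholds on the authors' calls and the comparison of count models were not run. Depth limits genes near the filter most.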

Other observations

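Of 22 measured glutathione S-transferases, 5 fell (Mgst3, Gsta4, Gstm1, Gsta3 and Gstm4), none rose and 20 had a negative log2 change, with a median of -0.59. Gsta3 went from 995.2 ± 97.6 FPKM to 628.3 ± 48.6 (mean ± SD of 3 libraries) and Mgst3 from 19.0 ± 3.20 to 6.42 ± 0.348, with log2 changes of -0.66 ± 0.11 and -1.48 ± 0.14 (SE, limma adjusted p = 0.0484 and 0.0181). With median-of-ratios scaling 2 of the family passed, and with quantile normalization 4, all lower. Nfe2l2, which encodes the transcription factor NRF2, also fell, from 38.5 ± 3.19 to 24.8 ± 0.614 (limma adjusted p = 0.0353). The families, Fisher's test and the tests of explanations under this heading were chosen after the values were seen, while the limma, camera and fry tests were planned. By Fisher's exact test against the other tested genes, two-sided, the share of genes that fell was higher in this family (p = 7.73e-07), which is not independent evidence since the family was picked for its changes.

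Among genes of complement and coagulation more rose than fell. Of 35 measured, C4a, F11, C9 and C8b rose, Mbl2 fell, and 29 had a positive log2 change, with a median of 0.22. C4a is annotated as a processed transcript. C9 went from 179.4 ± 10.8 FPKM to 300.2 ± 32.9, C8b from 60.5 ± 25.1 to 178.2 ± 21.8, and the lectin gene Mbl2 from 318.7 ± 26.02 to 194.8 ± 12.9 (limma adjusted p = 0.0339, 0.0484 and 0.0308). With median-of-ratios scaling 5 rose and 1 fell, and with quantile normalization 4 and 1. Among 19 major urinary protein genes, Mup12, Mup13 and Mup21 rose and Mup10 fell, and 16 had a positive log2 change, with a median of 1.51. With quantile normalization 1 of them rose and 1 fell, and with median-of-ratios scaling 4 rose and 1 fell.

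The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 151 genes, 43 higher and 108 lower, and was the 1 split of 10 with counts that large in each case, the highest of the others being 1 gene. It gave 14 lists, where another split gave 12, so camera with the preset correlation also called many lists in splits that mixed WT and HO. Each of the other splits held WT and HO in both groups. This leaves part of any real difference between the groups and moves the rest into the spread within them. Few gene calls would follow from that alone, and the list calls do not measure false calls.

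Male-biased genes rose as a list in HO, with 3 of 17 past the threshold (camera adjusted p = 8.87e-17, adjusted p = 0.385 with an estimated correlation and 0.0607 with fry), and 3 of 8 female-biased genes fell, while the female-biased Cyp2c40, with a log2 change of 1.53, did not pass (limma adjusted p = 0.0503). A female animal among the libraries is argued against by Xist, which reached at most 0.0522 FPKM. Reads moved between copies of a family would leave the family's summed FPKM unchanged, yet the sums changed along with Selenbp2, Serpina1e and Cyp2b9, by log2 ratios of 2.02, 0.84 and -2.39, the smallest size being 0.839, with no overlap between the groups. For Ugt2b38 and Cyp2a4 the sums changed by no more than 0.191 in size, since other copies dominate them, and a shift of reads cannot be told apart from a change of the gene. The genotype and a difference of genetic background, raised below for Nnt, stay among the open explanations and were not tested.

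More genes fell than rose, 71.5% of the calls. With median-of-ratios scaling the share of lower genes was 50%. That scaling moved the median log2 change of all genes from -0.09 to -0.01, which evens the directions whatever the cause of the excess, so the share decides nothing. A smaller share of non-hepatocyte cells in HO was weighed as the main source, without a decision. Of 60 pooled markers of Kupffer, endothelial, stellate, biliary, monocyte and lymphoid cells, 98.3% fell by less than the median gene called lower (-1.02) or did not fall, and their median was -0.25. With erythroid, adipocyte and neutrophil markers added, the share was 95.95% of 74 markers. The genes called lower were picked for their falls in these same data, so most genes fall by less than they do, and these shares decide nothing. Of the 60 markers, 53 had a negative log2 change, against 64.6% of all tested genes, so a loss of such cells stays open. Scaling and a real shift of many genes in HO cannot be told apart with these values.

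Nnt was lower in all 3 HO libraries. A different division of reads among its 6 annotated isoforms is argued against, since the longest is 1.84 times the shortest and the smallest fold of any WT over any HO library was 16.4. C57BL/6J mice carry a deletion in Nnt that substrains such as C57BL/6N lack, and Nnt lies 21.8 Mb from Lncenc1. An allele carried along with the mutation or from another substrain is therefore a candidate explanation. It cannot be told apart from an effect of Lncenc1, because the labels give no substrain. A difference of substrain would not be limited to Nnt, so the same holds for the other genes and lists that differed in HO. Within 25 Mb of Lncenc1 on either side, 1 of 177 tested genes changed, which is Nnt. Among all tested genes 151 of 13250 changed, and the 2 shares did not differ (Fisher's exact test, two-sided, p = 0.726). The window, which is wide enough to hold Nnt, was chosen after the values were seen. This count therefore says nothing for or against an effect on nearby genes or a linked allele.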
